A study of Mus musculus with 2 samples.

How the data were processed

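Total RNA of sorted LT-HSC and MPP was digested with RNase R, amplified with random primers into Cy3-labelled cRNA and hybridised (1 µg for 17 hours at 65 °C) to a mouse circRNA array, per the labels' protocols. The labels do not say how many mice or cells stand behind each sample. The design gives 1 array per population, assigned from the cell type label.

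The scanner files hold spot intensity values that the authors made with Agilent Feature Extraction 11.0.1.1 in its single-colour protocol, per the file headers. The genome build named for the array design is mm9, per the file headers; no coordinates were used. The processed signal is background-subtracted and spatially detrended. On the MPP array it also differed from the background-subtracted signal by more than 1% for 63.3% of circRNA spots well above background, against 0% on the LT-HSC array, so a multiplicative correction had acted on one array only. Over these MPP spots the ratio of processed to background-subtracted signal had a median of 0.999. Its central 95% ran from 0.953 to 1.045, which is small beside a 2-fold difference. The deposited series table holds log2 values for 1136 of the 1797 circRNA probes; its log base and normalization are not given in the sources used here. Set against the scanner values, its columns followed the quantile-normalized log2 of spot median minus local background with slopes of 0.97 and 0.99 (Pearson r of 1.00 on both arrays), so the scale is log2, not centred, and the direction is unchanged. Its columns have medians of 6.49 and 6.54.

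The main values are the log2 of the processed signal. Spots marked as outliers were left out (3.33% of circRNA spots on the LT-HSC array, 1.46% on the MPP array), no spot was saturated, and the spots of a probe were averaged on the log2 scale. Each array's 75th percentile over the 1797 circRNA probes was subtracted, because most of them were detected; the percentiles were 7.08 and 6.47, so the arrays differed by 0.61 before scaling. A probe counted as well above background when more than 0.5 of its spots carried the scanner's flag. Differences are LT-HSC minus MPP, and 2-fold (1 on the log2 scale) was the threshold. With 1 array per group no test was run, and the number of arrays limits the precision. In simulated data with 1048 probes and the measured spot noise, 50 of 50 probes planted at 3-fold passed 2-fold, 0 of 50 planted at 1.5-fold did, and 0 of 848 unchanged probes did; this checks the computation and the spot noise, not variation between animals.

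The circRNA probes carry identifiers that neither the files nor the gene table used here pairs with a circRNA or host gene. The 7 pathway lists and 7 cell type marker lists fixed before the data were examined (HSC regulators, chromatin, cell cycle, DNA damage, nucleic acid sensing, splicing, ubiquitin, and markers of myeloid, erythroid, megakaryocyte, B, T/NK, stromal and neuronal cells) therefore gave no result, nor did the planned comparison of circRNAs from one host gene or the look-up of 1 circRNA number recalled from the study's later work. The fixed rule for named probes took the 12 largest differences per direction whose spots did not overlap; because the identifiers carry no name, only the first 2 of each 12 are printed. Its parts on the brightest probes and on probes measured on 1 array only are given without identifiers or left out, since brightness is not comparable between probes. The transcript probes were added after the values were seen, and all past 2-fold with a gene symbol are named. Accessions were matched without versions to the RefSeq gene table of assembly GRCm38.p6, which named 44 of 50; the other 6 are not named.

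Alternatives were other scalings (quantile, median, percentile over detected probes, lowess), background corrections, filters, fold thresholds, spot averages and the authors' deposited log2 table. Normexp used limma 3.58.1 in R 4.3.3 with an offset of 50 on the spot median, since the files have no mean signal. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. Matched lists were drawn 10000 times within bins of mean signal.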

Results

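Circular RNA was profiled in a pair of cell populations sorted from the bone marrow of wild-type C57/BL6 mice aged 8 weeks: long-term haematopoietic stem cells (LT-HSC), the self-renewing cells at the top of the blood lineage, and multipotent progenitors (MPP), which descend from them and have lost long-term self-renewal. Circular RNAs (circRNAs) are transcripts whose ends are joined by back-splicing, which leaves them resistant to the exonuclease RNase R. One single-colour array was hybridised per population, so the design holds 2 samples with 1 in each group. No difference between the populations had a replicate check, no p-value could be given, and errors are SDs over the replicate spots of a probe within an array, which are technical. Each array carried 1797 circRNA probes with 7 spots each. The 2 arrays were scanned on different days, so the scan day and the population cannot be told apart.

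The first comparison asks which circRNAs were measured in each population. On the LT-HSC array 1192 of the 1797 circRNA probes (66.3%) gave signal well above background, and on the MPP array 1161 did (64.6%). Both arrays measured 1048 of these probes. Another 144 were well above background on the LT-HSC array only, and 113 on the MPP array only. This threshold is not specific to circRNAs, since 16 of 40 probes named as negatives also passed it on the LT-HSC array and 10 of 40 on the MPP array. The median SD over the spots of a probe was 0.07 on the log2 scale on the LT-HSC array and 0.10 on the MPP array, over the 1048 probes measured on both.

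The second comparison asks which circRNAs differed in abundance between LT-HSC and MPP. Of the 1048 circRNAs measured on both arrays, 254 (24.2%) were at least 2-fold higher in the LT-HSC sample, 219 (20.9%) were at least 2-fold higher in the MPP sample, and 575 (54.9%) lay within 2-fold. Small and large differences were not distributed alike. At least 4-fold, 45 circRNAs were higher in LT-HSC and 98 in MPP; at least 8-fold, the counts were 4 and 61; at least 16-fold, they were 0 and 28. The direction also varied with signal. At 2-fold MPP led only in the brightest of 5 bins of mean signal (67 against 44 in LT-HSC), and LT-HSC led in the others. Over the 1048 circRNAs the log2 signals spread more on the MPP array (SD 2.26) than on the LT-HSC array (SD 2.01). The sizes of the 8-fold counts depended on the processing, from 0 to 8 in LT-HSC and from 24 to 100 in MPP, but MPP held more under each of 8 other scalings and background corrections. No gene or circRNA name could be attached to these probes from the tables used here, so they are given by probe identifier.

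**Figure D1:**
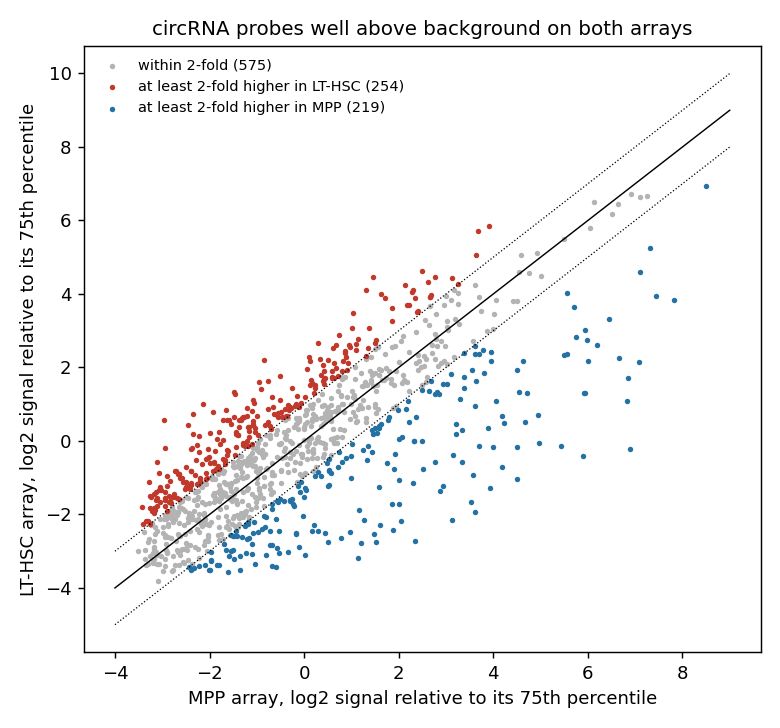
Each point is one of the 1048 circRNA probes well above background on both arrays, with its log2 signal relative to the 75th percentile of the MPP array (x axis) and of the LT-HSC array (y axis); the solid line is equality and the dotted lines 2-fold. The 219 probes at least 2-fold higher in MPP reach much farther from the line than the 254 at least 2-fold higher in LT-HSC.

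Among circRNAs measured on both arrays whose spots did not overlap, probe ASCRMP001268 had the largest difference in favour of MPP. Its processed signal was 117 on the LT-HSC array and 10570 on the MPP array, a difference of -7.11 (LT-HSC minus MPP, log2 after scaling) or 138-fold, with an SD over spots of 0.03 and 0.06 (n = 7 spots on each array). Probe ASCRMP001489 was 79.2-fold higher in MPP, at -6.31, with SDs of 0.07 and 0.06. In the opposite direction, probe ASCRMP001675 was 11.7-fold higher in LT-HSC, at 3.54, with a signal of 201 against 11.3 and SDs of 0.05 and 0.20. Probe ASCRMP000465 was 8.89-fold higher in LT-HSC, at 3.15, with a signal of 274 against 20.2 and SDs of 0.04 and 0.12. On the array where it was dimmer, each of these 4 probes lay below the 95th percentile of the negative-named probes (121 on the LT-HSC array and 54.3 on the MPP array), so the size of its fold is uncertain. Of the 413 circRNAs above that level on both arrays, 0 were at least 8-fold higher in LT-HSC and 27 in MPP. Normexp background correction with an offset of 50 gave the smallest differences among the alternatives. They were 1.51 for ASCRMP001675 and 1.68 for ASCRMP000465 with the 75th percentile, and -5.82 for ASCRMP001268 and -4.77 for ASCRMP001489 with quantile normalization. Among the 12 circRNAs per direction with the largest differences and no overlap of spots, the folds ran from 32.9 to 138 in MPP and from 5.86 to 11.7 in LT-HSC. Their dimmer signals ran from 20.4 to 448 on the LT-HSC array and from 11.3 to 244 on the MPP array. In both directions most lay below the 95th percentile of the negative-named probes, so most of these folds are uncertain too.

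These differences were large beside the spot noise. The spots of the 2 arrays did not overlap for 850 of the 1048 circRNAs (81.1%), and among these 252 were at least 2-fold higher in LT-HSC and 214 in MPP. The median SD of a difference over spots was 0.14 on the log2 scale, against an SD of 1.52 for the differences across circRNAs. Spot noise holds no error between arrays. Across the 9 negative-named probes measured on both arrays the differences had an SD of 0.91. Of these 9, 4 were at least 2-fold higher in LT-HSC and 0 in MPP. The SD was 0.87 across 5 ERCC-named probes and 1.83 across 6 probes named as circRNA controls. Across the 1048 probes, which are not independent replicates, the log2 signals of the arrays correlated with a Pearson r of 0.75 and a Spearman rho of 0.75. The median difference was 0.19 towards LT-HSC and ran from -0.03 to 0.37 under the alternatives, so which direction held more calls depends on the scaling, and it also turned without a filter on dim probes (373 in LT-HSC and 409 in MPP). LT-HSC held 53.7% of the 2-fold calls here, 63.4% with the percentile taken over probes detected on both arrays, 46.2% with each array centred on its median, and 44.4% with a lowess correction. Starting from the spot median with normexp background correction, the counts were 109 in LT-HSC and 120 in MPP with the 75th percentile, and 132 and 103 with quantile normalization.

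**Figure D2:**
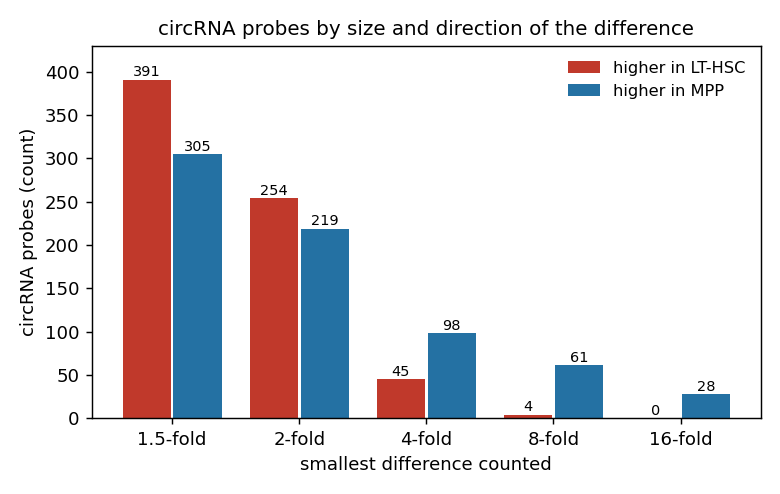
Bars give the number of circRNA probes (y axis, count) whose signal was higher in the LT-HSC sample (red) or in the MPP sample (blue) by at least the fold on the x axis. LT-HSC leads at 1.5-fold (391 against 305) and at 2-fold (254 against 219), although at 2-fold the leading direction turns under median centring, under lowess, with normexp and the 75th percentile, and without a filter on dim probes; MPP leads from 4-fold upwards.

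For circRNAs measured on 1 array only, the fold is a bound. It is set against the higher of the dim probe's own signal and the lowest signal well above background on that array. Where the dim probe's own signal was the higher, the bound is the measured fold and not a lower bound. Of the 144 circRNAs well above background on the LT-HSC array only, 125 were higher there by this bound. Among them 51 were at least 2-fold higher and 8 at least 4-fold. Of the 113 on the MPP array only, 67 were at least 2-fold higher and 32 at least 4-fold. These counts are not specific to circRNAs. Of the 40 negative-named probes, 16 were well above background on the LT-HSC array, 10 on the MPP array and 9 on both. Bounds towards LT-HSC reached 3.53-fold for mmu_normal_negative_0004, and towards MPP 40.7-fold for mmu_normal_negative_0028. The largest bound was 9.31-fold in LT-HSC (signal 125 against 8.78) and at least 171-fold in MPP (signal 1055 against 6.85). The 9.31-fold is a measured fold, because 8.78 lies above the lowest signal well above background on the MPP array (7.77). The 40.7-fold of mmu_normal_negative_0028 is a measured fold as well.

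The arrays also carried 50 probes named by a messenger or non-coding transcript, 44 of which could be matched to a gene symbol. The files do not say whether their signal after RNase R digestion came from linear RNA or a circRNA of the same gene, or was non-specific. The highest signals were those of olfactory receptor probes, Olfr1307 on the LT-HSC array (6693) and Olfr166 on the MPP array (1951). The Actb probe gave 10.71 on the LT-HSC array and 11.02 on the MPP array. Brightness is not comparable between probes, so these values do not decide the source. Of the 50 transcript probes 43 were well above background on both arrays. Relative to the circRNA scaling, 19 of the 43 were at least 2-fold higher in the LT-HSC sample, 4 were at least 2-fold higher in the MPP sample, and 20 lay within 2-fold. Their median difference was 0.87, and 32 of 43 were positive. That median stood at the 99.85th percentile of 10000 random lists of circRNA probes matched on signal, whose central value was 0.14; this describes these 2 arrays and is no test of the populations. Probes named as negatives stood on the same side, with a median of 0.79 over the 9 measured on both arrays, of which 4 were at least 2-fold higher in LT-HSC and 0 in MPP. The 5 probes named for ERCC sequences and measured on both arrays had a median of 0.67. The transcript median was 0.36 with normexp on spot medians and the 75th percentile, which left 12 probes at least 2-fold higher in LT-HSC and 1 in MPP.

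The transcript probes with the largest differences towards LT-HSC were Prdx2, which encodes a peroxiredoxin that removes hydrogen peroxide (5.92-fold, 2.57 ± 0.04 log2), and Pex11a, a peroxisome membrane protein that takes part in peroxisome division (5.24-fold, 2.39 ± 0.05). The error here is the SD of the difference over spots, with 6 to 10 spots per probe and array. Uhrf1bp1l followed at 4.08-fold (2.03 ± 0.36) and Carhsp1, an RNA-binding cold-shock domain protein, at 3.94-fold (1.98 ± 0.07). Gsdmd, the pore-forming protein of pyroptosis, was 3.61-fold higher. Alkbh4 was 3.54-fold, Spats1 3.44-fold and Chgb, a secretory granule protein, 3.01-fold higher. Acaa2, the mitochondrial thiolase of fatty acid beta-oxidation, was 3.23-fold higher, and Ppara, a nuclear receptor that controls fatty acid oxidation genes, 2.93-fold higher. Duox1, a hydrogen peroxide producing oxidase, was 2.72-fold higher and Rab5a, the small GTPase of early endosomes, 2.71-fold higher. Olfr1307, an olfactory receptor, was 2.70-fold, Lhfp 2.38-fold, Anxa8 2.32-fold, Atg3, an enzyme of autophagosome formation, 2.17-fold and Dnajc11 2.05-fold higher. The differences of Uhrf1bp1l, Chgb, Ppara, Lhfp, Anxa8, Atg3 and Dnajc11 were below 2-fold under at least one other scaling or background correction. The signals of Uhrf1bp1l, Ppara, Lhfp, Anxa8 and Dnajc11 lay below the 95th percentile of the negative-named probes on both arrays, and those of Gsdmd and Chgb did on the MPP array. Quantile normalization gave larger differences for Prdx2 (3.45), Pex11a (3.38), Acaa2 (2.64), Duox1 (2.49) and Olfr1307 (2.30), and normexp with the 75th percentile a smaller one for Gsdmd (1.22).

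In the opposite direction, 4 transcript probes were at least 2-fold higher in the MPP sample. Mzb1, an endoplasmic reticulum protein of B-lineage cells, was 3.30-fold higher in MPP (-1.72 ± 0.11), and Hspb7, a small heat shock protein of heart muscle, 2.98-fold higher (-1.58 ± 0.14). H2-Q7, a non-classical MHC class I gene, was 2.54-fold higher (-1.34 ± 0.08), but its signal is uncertain because the family has near-identical members. Lhx1, a LIM homeobox transcription factor, was 2.05-fold higher (-1.04 ± 0.12). Hspb7, H2-Q7 and Lhx1 were below 2-fold under at least one alternative, and Mzb1 was not, with -1.13 as its smallest difference. Mzb1 and Hspb7 lay below the 95th percentile of the negative-named probes on the LT-HSC array. The 17 named probes within 2-fold ran from Apoe, the apolipoprotein of lipid transport, at -0.99 to Rps4l at 0.97. Kcnn2 was well above background on the LT-HSC array only and was at least 2.09-fold higher there, with a signal of 24.8, which is also below the 95th percentile of the negative-named probes. None of the 44 transcript probes with a gene symbol belonged to a gene of the pathway or cell type marker lists fixed beforehand.

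**Figure D3:**
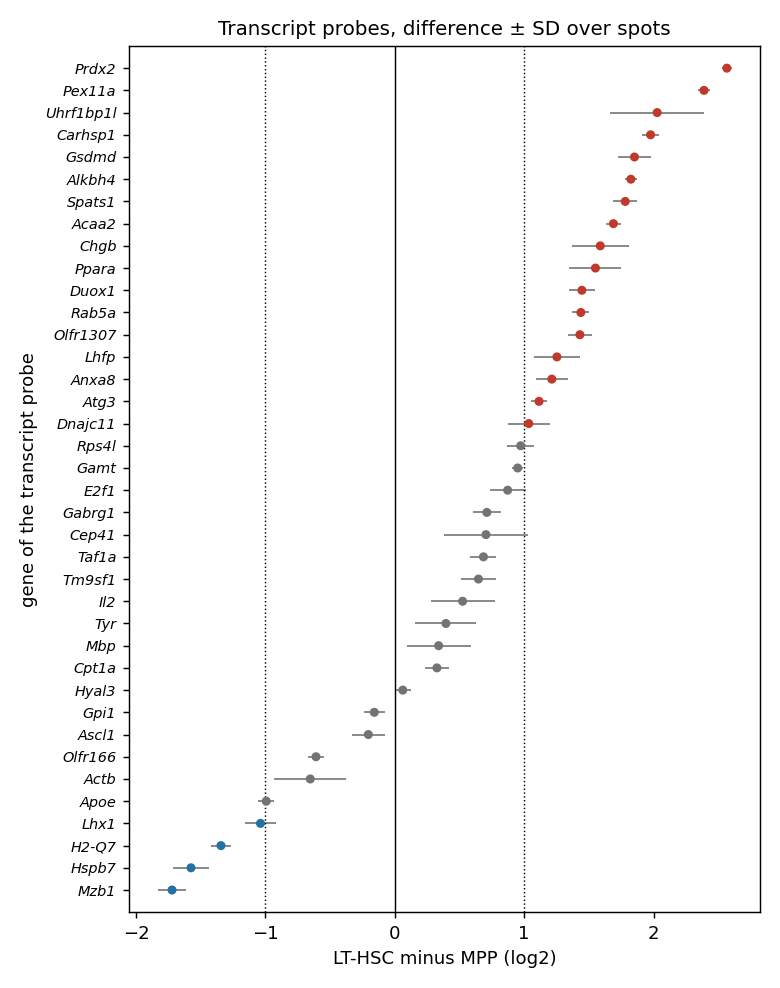
Points give the LT-HSC minus MPP difference (x axis, log2) of the transcript probes with a gene symbol that were well above background on both arrays (y axis, gene), with bars for the SD over spots; dotted lines mark 2-fold. The 17 named genes in red lie at least 2-fold towards LT-HSC, from Dnajc11 to Prdx2, and the 4 in blue at least 2-fold towards MPP.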

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

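Probes outside the circRNA comparison gave signal. Among 40 probes named as negatives, 16 were well above background on the LT-HSC array and 10 on the MPP array, whereas 2 and 0 of the scanner's own 77 negative control spots were. Of 18 probes named for ERCC sequences, 8 were well above background on the LT-HSC array and 5 on the MPP array; no label states that such RNA was added. One negative-named probe, mmu_normal_negative_0028, had a signal of 259.7 on the MPP array and 9.76 on the LT-HSC array. It was not well above background on the LT-HSC array, and its measured fold was 40.7 towards MPP. Its SD over 20 spots was 0.12 on the MPP array and 0.37 on the LT-HSC array, on the log2 scale. It was singled out after its values were seen.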

How the results depend on the processing

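Normexp, lowess, the negative-named level, local background only, keeping outlier spots, the 8-fold counts, every alternative for transcript probes, other scalings for the correlation of the arrays, and other spot averages and the percentile over detected probes for the named circRNAs were chosen after seeing the data. No paired analysis was possible because each group has 1 sample, and no replicate could be left out. Of 120 alternative values of the summary results, 87 stayed within 1.5 times the count or within a bootstrap interval over probes. Counts at 2-fold in LT-HSC and MPP were 109 and 120 with normexp and the 75th percentile, 132 and 103 with normexp and quantiles, and 98 and 82 above the 95th percentile of negative-named probes (413 probes left). The authors' deposited table gave 156 in LT-HSC, and no filter gave 373 in LT-HSC and 409 in MPP. Thresholds of 1.5-fold and 4-fold gave 391 and 45 in LT-HSC, and 4-fold gave 98 in MPP. At 8-fold the LT-HSC count was 8 with quantiles, 7 with the percentile over detected probes, with even-numbered spots, without a filter and with detection on at least one array, 2 with median centring, lowess and the authors' table, and 0 with normexp and the percentile or above the negative-named probes. The MPP count at 8-fold was 33 and 24 with normexp and the percentile or quantiles, 35 in the authors' table, 33 with local background only, 100 without a filter or with detection on at least one array, and 27 above the negative-named probes. The correlation of the arrays was 0.854 over all probes. Normexp and the percentile gave a transcript median of 0.36 with 12 and 1 probes past 2-fold, and 1 in MPP also with quantiles. Fewer probes remain by construction above the negative-named level, and the offset of 50 shrinks dim differences. Normexp also started from the spot median, and that signal less local background, with quantiles and no offset, gave 186 and 149; other causes were not tested. None of 279 alternative values of the 25 named probes changed direction, and 244 stayed past 2-fold. These probes were picked for large differences on the same 2 arrays, so a change of direction was unlikely from the start. Under quantiles 242 of the 254 LT-HSC calls and 204 of the 219 MPP calls were shared. Far fewer were shared under other settings. The shared LT-HSC and MPP calls were 104 and 120 with normexp and the 75th percentile, and 108 and 103 with normexp and quantiles. In the authors' table, which holds 992 of the 1048 probes, 136 and 153 were shared. No spot was saturated, so leaving such spots out changed nothing and is not counted. The planned normexp on mean signals and all host-gene alternatives were not run.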

Other observations

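Of the tests reported here, only the one on matched signal was chosen before its result was seen. The transcript probes that it was applied to had been added after their values were seen. A further 14 probes carried names of circRNA controls, and what they target is not given in the sources used here. Of these, 6 were well above background on both arrays, 2 on the LT-HSC array only and 2 on the MPP array only. AS_circRNA_control006 was 4.07-fold and AS_circRNA_control013 3.75-fold higher in LT-HSC, and AS_circRNA_control003 was 7.57-fold higher in MPP. In MPP only, AS_circRNA_control011 (signal 206 against 2.72) was at least 33.3-fold and AS_circRNA_control008 at least 4.30-fold higher. In LT-HSC only, AS_circRNA_control014 (signal 51.3 against 2.98) was at least 4.32-fold higher and AS_circRNA_control007 higher by at least 0.58 on the log2 scale. The dimmer signals of AS_circRNA_control006, AS_circRNA_control013 and AS_circRNA_control003 (40.6, 40.2 and 11.2) lay below the 95th percentile of the negative-named probes. These probes were singled out after their values were seen.

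More circRNAs were at least 8-fold higher in MPP (61) than in LT-HSC (4). The scaling between arrays is argued against as the whole cause, because the smallest ratio of the MPP to the LT-HSC count over 8 other scalings and background corrections was 6.125. That ratio came with quantile normalization, and lowess gave 30.5. Median centring and the percentile over detected probes shift every difference by a small constant, so they could hardly change the ratio. The authors' table is nearly the same setting as local background only with quantiles (Pearson r of 0.999 between differences). Faults of single spots are argued against as well, because 57 of the 61 probes (93.4%) kept the 8-fold difference in odd-numbered and even-numbered spots alike. The 61 probes were picked on the mean of the same spots, which favours this result. A fault shared by all spots of a probe was not tested. Uneven amplification, the scan day and a difference between the cell populations cannot be told apart with 1 array per population. Non-specific signal was not tested as a cause of this pattern. The largest bounds towards MPP were 40.7-fold among negative-named probes and 33.3-fold among circRNA control-named probes. Towards LT-HSC the largest bounds were 3.53-fold and 4.32-fold. A candidate explanation in biology, that MPP carry a set of circRNAs which LT-HSC hold at far lower levels, stays an untested hypothesis, which replicate arrays of each population would be needed to decide.

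Transcript probes sat higher on the LT-HSC array relative to circRNA probes, by 0.68 on the log2 scale between the medians, and by 0.34 to 0.75 under the alternatives that hold these probes. For the main values a trend of the scaling with signal is argued against, because the transcript median lay at the 99.85th percentile of circRNA lists matched on signal. That percentile was not computed under the alternatives. With normexp the gap between the medians was 0.39 with the 75th percentile and 0.34 with quantiles. In the same comparison the median of the 9 negative-named probes stood at a percentile of 86.93. More non-specific signal on the LT-HSC array stays open: the transcript median exceeded that of the 9 negative-named probes measured on both arrays by 0.086, with a 95% bootstrap interval from -0.75 to 1.16, too wide to decide. This comparison also left out negative-named probes well above background on 1 array only. Of all 40, 16 passed on the LT-HSC array and 10 on the MPP array. More linear RNA left after RNase R in the LT-HSC sample may also be part of it, as may a difference between the cell populations; neither was tested.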
